A study of Homo sapiens with 6 samples.

How the data were processed

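The deposited table covers 6 mRNA libraries of C666-1 cells sequenced on an MGI instrument, 3 from complete medium and 3 from the same medium without serine and glycine, each after 24 h. Per the labels' protocols, RNA was extracted with Trizol, mRNA was fragmented and copied to cDNA, and the ligated and amplified product was circularised. The labels do not say whether the library kit kept strand, so reads of overlapping antisense genes cannot be told apart. Both media held 4.5 g/L glucose and 10% dialyzed serum, per the labels' protocols. Groups and replicate numbers come from the sample titles and treatment labels.

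Per the submitters' processing notes, Bowtie2 2.3.4.3, RSEM 1.3.1 and the GRCh38 build were used, with no role or order given. The annotation release is not given in the sources used here. The authors deposited expected counts per gene, estimates that need not be whole, and 15.2 to 16.0% of the values per library were not whole numbers. The authors also deposited FPKM values, scaled by gene length and library depth, and TPM values, whose total is the same in each library. The authors' mean columns matched the mean of the 3 libraries of each medium within 3.3e-05 and were not used in any test. Of 16407 genes in the table, 16352 had their NCBI Gene number in the RefSeq gene table for GRCh38, 16116 had the same symbol there, and 16298 were protein-coding. Positions are from that table. Multi-mapping reads that an expectation-maximisation counter divides between similar genes make the values of close paralogs uncertain.

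Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12548. Libraries were scaled by TMM, with factors from 0.978 to 1.025. The quasi-likelihood fit was robust, with medium as the one term, and p-values were two-sided and adjusted by Benjamini-Hochberg over the tested genes, with a call at 0.05. The common biological coefficient of variation was 8.43%. A second count took called genes with an absolute log2 fold change of at least 1. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. Log2 fold changes are those without serine and glycine relative to complete medium. Their SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It is thus derived from the test and is not independent of the p-value.

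The 36 gene lists, the naming rule and the main test were fixed before the data were examined. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 34 lists. Each list was also tested with an estimated correlation and with fry. The rule for named genes took the 10 largest rises and falls among called genes with at least 5 CPM in the higher group and no overlap between the media, the 5 smallest p-values in each direction, a fixed set of serine, folate, amino acid response and macrophage attractant genes, and up to 4 members of each list by smallest adjusted p. One gene of the fixed set is not analysed here, and some list members that the rule takes are not reported here by name.

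The libraries held 16612189 to 17030352 counts. The 10 most abundant genes took 3.49 to 4.04% of the counts. Replicates of a medium differed by far more than sampling noise (chi-square per gene of 2.76 to 19.1), so no library was counted as a copy of another. Pairs from different media gave 9.26 to 34, so some were closer than some replicates. The labels give both media the replicate numbers 1 to 3 and do not say that a number marks a shared day or batch. Deviations from the group means correlated across genes between same-numbered libraries at 0.326, 0.141 and 0.190, each above the minimum of 0.1 set for pairing, while pairs of different number ranged from -0.282 to 0.163. The value of 0.163, for library 3 of complete medium with library 2 of the deprived medium, also passes that minimum and exceeds the 0.141 of the libraries numbered 2. The criterion therefore does not settle whether the numbers pair the libraries. A fit with the number as a block is given beside results for genes and fixed lists whose call it changes or whose count it moves by over 1.5 times.

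The edgeR procedure was tested on simulated counts for this comparison, 12548 genes in 3 against 3 libraries. It recovered 87 of 100 genes changed 1.5-fold and 97 of 100 changed 2-fold, with 26 false calls among 210. That share of false calls is above the adjusted 0.05 at which genes were called. The changed genes were drawn from those with a mean over 5 CPM, so the recovery does not cover rarer genes. Camera called 4 of 100 random lists of 20 simulated genes at an unadjusted 0.05. The lists were drawn from all simulated genes, changed ones included. Counts were drawn independently for each gene, so this does not test how camera behaves when genes vary together.

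Alternatives fixed before the data were examined were DESeq2's size factors, library totals alone, no filter on low counts, at least 1 CPM in 3 libraries, the block, leaving out each library in turn, limma on log2(FPKM + 1) and log2(TPM + 1), limma voom, DESeq2 1.42.0 and a test against a 1.2-fold change. Added after seeing the data were the block with a per-library correction for GC content and transcript length, leaving out both libraries numbered 1, and the block with 1 pair left out. Transcript length and GC content came from the longest protein-coding GENCODE transcript and were found for 99.3% of tested genes. Figures were drawn in Python 3.11.15.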

Results

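RNA was measured in C666-1, a human nasopharyngeal carcinoma cell line that carries Epstein-Barr virus, after 24 h in 1 of 2 media. Complete medium was a minimal essential medium without the usual non-essential amino acids, to which 0.4 mM serine and 0.4 mM glycine had been added. The other medium lacked serine and glycine and was otherwise the same. Each medium had 3 libraries, numbered 1 to 3 in the labels. The libraries of complete medium held 16612189, 16902732 and 16876088 estimated counts over 16407 genes, and those without serine and glycine held 16756358, 16676295 and 17030352. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The title of the series places serine, from outside and inside the cell, in the setting of tumour-associated macrophages, and the design asks how the tumour cells' transcripts respond when both amino acids are withdrawn.

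Withdrawal of serine and glycine was followed by many small changes. Of 12548 genes tested, 343 were higher and 529 were lower without serine and glycine, 872 in all, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The median absolute log2 change of these 872 genes was 0.40, and 38 changed at least 2-fold, 27 of them higher and 11 lower. The 2-fold count of 38 varied with the method: DESeq2 gave 21, limma on log2(FPKM + 1) 6, limma on log2(TPM + 1) 7, and a test against a fold of 1.2 called 0 genes. DESeq2 and limma on FPKM or TPM also differed from the main fit in the genes tested, and FPKM and TPM in scale. Some genes of glycolysis, glutathione synthesis, the folate cycle, nucleotide synthesis and tRNA charging were among those that fell. Some targets of p53 were among those that rose. With the shared replicate numbers as a block, 3044 genes were called, 1387 higher and 1657 lower, with 80 changed at least 2-fold, and all 872 genes were among the 3044 with the same sign. Without replicate 2 or 3 of complete medium, or replicate 2 or 3 of the deprived medium, edgeR called 0 genes each time, and so 0 changed at least 2-fold. At an unadjusted p under 0.05 these 4 fits held 2173, 2494, 2846 and 2624 genes, limma voom called 0 in each, and DESeq2 called 232, 408, 590 and 401. Every gene called by edgeR kept its sign in the 6 fits that left out 1 library. Those fits share their libraries with the main fit, so this is not independent evidence. Without replicate 1 of complete medium 1318 genes were called, and without replicate 1 of the deprived medium 1737. Without both libraries numbered 1, a setting chosen after seeing the data, 3643 genes were called, while limma on log2(FPKM + 1) called 506 and on log2(TPM + 1) 148. Fits with the block or with libraries left out have less from which to estimate the spread, so their higher counts are not stronger evidence.

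**Figure D1:**
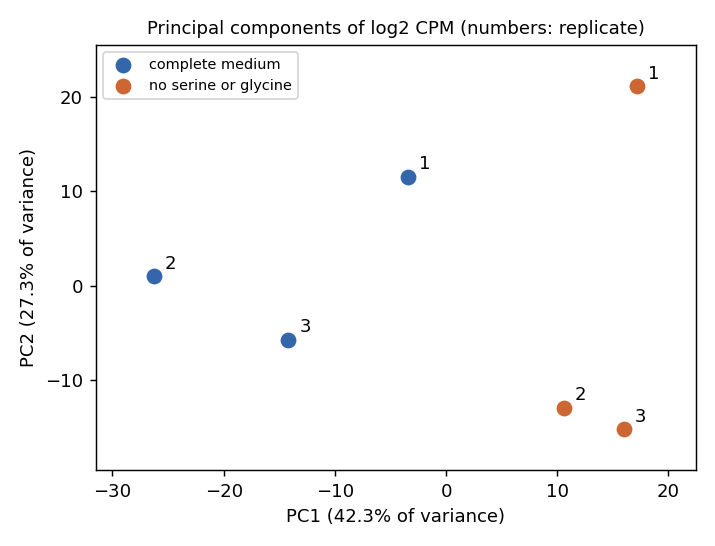
Principal components of log2 CPM over the tested genes, with 1 point per library, coloured by medium and marked with its replicate number. The first component (x axis, 42.3% of the variance) puts the complete-medium libraries at -26.28 to -3.38 and the deprived libraries at 10.59 to 17.21, while the second (y axis, 27.3%) puts the libraries numbered 1 highest in each medium, at 11.57 and 21.18.

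Enzymes that make serine from glucose carbon did not pass the test. PHGDH, which catalyses the first step from 3-phosphoglycerate (NCBI Gene 26227, chromosome 1, 119711934 to 119744215 on GRCh38), was at 532.5 ± 36.7 CPM (SD, n = 3) in complete medium and 515.2 ± 52.0 CPM without serine and glycine, a log2 change of -0.05 (SE 0.088, adjusted p = 0.762). PSAT1, the next enzyme, was at 1167 ± 103 and 1025 ± 56.5 CPM, a log2 change of -0.19 (SE 0.085, adjusted p = 0.184, and 0.0209 with the replicate block). PSPH, the last, had a log2 change of -0.27 (SE 0.070, adjusted p = 0.0504, and 0.00603 with the block). Of these 3 genes, 0 were called over all genes tested, 1 was lower when adjusted over the list alone, and 2 were lower with the block. The list did not pass the camera test (adjusted p = 0.214).

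Genes that pass serine's carbon into folates fell in part. Of 19 tested genes of serine-glycine interconversion and the folate cycle, 4 were lower and 0 higher over all genes tested, 8 were lower adjusted over the list alone, and 9 were lower with the block. FPGS, which adds glutamates to folate, fell from 48.4 ± 5.68 to 29.2 ± 3.41 CPM (n = 3), a log2 change of -0.73 (SE 0.109, adjusted p = 0.0217). MTHFD1, TYMS and MTHFD1L fell by 0.34, 0.35 and 0.32 on the log2 scale, with adjusted p of 0.0246, 0.0317 and 0.0340. The hydroxymethyltransferases that interconvert serine and glycine were not called. SHMT1 had a log2 change of -0.19 (adjusted p = 0.0844, and 0.0307 with the block) and SHMT2 one of -0.05 (adjusted p = 0.699). MTHFD2 had a log2 change of -0.25 (adjusted p = 0.0832, and 0.00523 with the block). The list was lower by camera with a preset correlation of 0.01 (adjusted p = 0.00591, median log2 change -0.15). With an estimated correlation its adjusted p was 0.613.

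Of 9 tested genes of the methionine cycle and transsulfuration, 3 were lower and 0 higher over all genes tested, 4 were lower adjusted over the list alone and 4 with the block. CBS, which joins serine to homocysteine, fell from 169.8 ± 9.97 to 122.7 ± 6.15 CPM, a log2 change of -0.47 (SE 0.066, adjusted p = 0.0196). CTH, which cleaves the product to cysteine, fell by 0.39 (adjusted p = 0.0276), and AHCY by 0.36 (adjusted p = 0.0393). The camera test gave an adjusted p of 0.0385 for the list, and 0.735 with an estimated correlation. This call was lost by the direction test of fry, which looks at the list's own genes alone (adjusted p = 0.153), without replicate 2 or 3 of complete medium (adjusted p = 0.157 and 0.0538) and without replicate 1 of the deprived medium (0.145), and with no filter on low counts (0.0771). Of 14 tested glutathione genes, 3 were lower over all genes tested, 8 adjusted over the list alone and 7 with the block, and 100% of them had a negative log2 change. GSTO1 fell by 0.53 (adjusted p = 0.0246), GSS, the glutathione synthetase, fell by 0.41 (adjusted p = 0.0246), and OPLAH, at 1.64 and 0.786 CPM, fell by 1.06 (adjusted p = 0.0478, and 0.0526 when libraries were scaled by their totals). The glutathione list passed camera (adjusted p = 0.000288). With an estimated correlation its adjusted p was 0.613.

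Textbook targets of ATF4, the transcription factor that raises amino acid synthesis and transport genes when amino acids are short, were lower or not called. Of 30 tested members, 5 were lower and 0 higher over all genes tested. Adjusted over the list alone, 7 were lower and 2 higher, and with the block 11 were lower and 2 higher. ASNS, the asparagine synthetase (NCBI Gene 440, chromosome 7, 97851677 to 97928441), fell from 611.3 ± 117 to 407.2 ± 48.2 CPM (n = 3), a log2 change of -0.59 (SE 0.142, adjusted p = 0.0443, and 0.0638 with no filter on low counts). PCK2, a mitochondrial enzyme of phosphoenolpyruvate synthesis, fell from 109.1 ± 24.3 to 63.2 ± 7.41 CPM (log2 change -0.79, adjusted p = 0.0339, and 0.0635 with no filter). FGF21, a secreted hormone, fell from 5.29 ± 1.44 to 2.36 ± 0.537 CPM (log2 change -1.16, adjusted p = 0.0314). STC2 was the remaining member that fell besides CTH, and was named after its values were seen (log2 change -0.31, adjusted p = 0.0444).

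Other members of the list were not called over all genes tested. ATF4 itself had a log2 change of 0.14 (SE 0.097, adjusted p = 0.396), DDIT3 one of 0.02 (adjusted p = 0.890) and TRIB3 one of 0.24 (SE 0.078, adjusted p = 0.0814, and 0.0273 with the block). KLHL24, also named after its values were seen, was at 51.5 CPM in complete medium and 76.5 CPM without serine and glycine. Its log2 change was 0.57 (SE 0.146, adjusted p = 0.0511, and 0.00123 with the block). CHAC1 had a log2 change of -0.35 (adjusted p = 0.0545, and 0.00778 with the block), and SESN2 one of -0.19 (adjusted p = 0.113, and 0.0360 with the block). The camera test gave an adjusted p of 0.0343 for the list, in the lower direction, and 0.735 with an estimated correlation. That call was lost by fry's direction test (adjusted p = 0.221), without replicate 2 or 3 of complete medium (adjusted p = 0.0788 and 0.0538), without replicate 1 of the deprived medium (0.373), and without both libraries numbered 1, a setting chosen after seeing the data (0.0911).

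**Figure D2:**
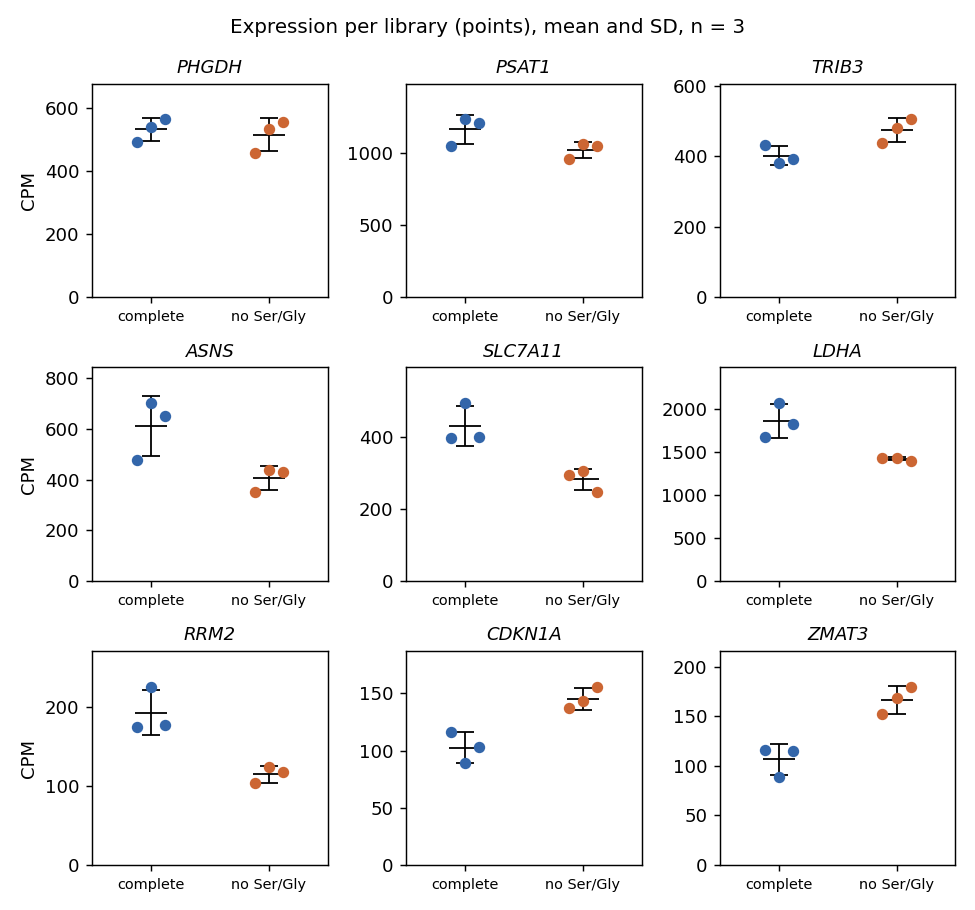
CPM of 9 genes in each library (points), with the mean and SD of the 3 libraries of each medium (bars), on linear axes that start at 0. PHGDH, PSAT1 and TRIB3 were not called, ASNS, SLC7A11, LDHA and RRM2 were lower, and CDKN1A and ZMAT3 were higher without serine and glycine.

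Most amino acid carriers were not called. Of 22 tested transporters, 3 were lower and 0 higher over all genes tested, and 3 were lower and 2 higher both adjusted over the list alone and with the block. SLC7A11, the cystine importer, fell from 430.0 ± 55.6 to 282.4 ± 29.8 CPM, a log2 change of -0.61 (SE 0.104, adjusted p = 0.0217, and 0.0967 without both libraries numbered 1). SLC43A1 fell by 0.60 (adjusted p = 0.0320) and SLC38A5 by 0.33 (adjusted p = 0.0273). SLC1A4, a carrier of serine and alanine, had a log2 change of -0.13 (adjusted p = 0.182), and SLC1A3 one of 0.39 (adjusted p = 0.0647, and 0.00141 with the block). The list's camera test had an adjusted p of 0.428, while fry's direction test gave 0.00105 in the lower direction.

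Cytosolic tRNA synthetases, which load amino acids onto tRNAs, were lower in part. Of 20 tested enzymes, 5 were lower and 0 higher over all genes tested, 11 were lower adjusted over the list alone and 12 with the block. VARS1, for valine, fell from 380.0 ± 10.9 to 284.0 ± 1.40 CPM, a log2 change of -0.42 (SE 0.058, adjusted p = 0.0184). GARS1, for glycine, fell from 865.2 ± 73.2 to 653.1 ± 26.7 CPM, a log2 change of -0.41 (adjusted p = 0.0246). FARSA, a subunit of the enzyme for phenylalanine, fell by 0.31 (adjusted p = 0.0251). The camera test gave an adjusted p of 1.89e-05. With an estimated correlation the list's adjusted p was 0.735, and by fry's direction test 0.0505. Of 23 tested chaperones and other genes of the endoplasmic reticulum stress response, DNAJB9 alone rose over all genes tested, by a log2 change of 0.37 (adjusted p = 0.0238). The counts were 3 higher and 2 lower adjusted over the list alone, 4 and 2 with the block, and the list's camera test had an adjusted p of 0.436.

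Some glycolytic genes fell. Of 22 tested genes, 8 were lower and 0 higher over all genes tested. The counts adjusted over the list alone were 14 lower and 1 higher, and with the block 18 were lower and 1 higher. LDHA, which reduces pyruvate to lactate, fell from 1862 ± 198 to 1424 ± 17.5 CPM (n = 3), a log2 change of -0.39 (SE 0.088, adjusted p = 0.0336). SLC16A3, which exports lactate, fell from 327.5 ± 28.9 to 222.6 ± 10.9 CPM (log2 change -0.56, adjusted p = 0.0184). PFKL, a subunit of phosphofructokinase, fell by 0.61 (adjusted p = 0.0217), and the glucose carrier SLC2A1 by 0.32 (adjusted p = 0.0271). The median log2 change of the list was -0.26 and its camera adjusted p 1.37e-05. With an estimated correlation the adjusted p was 0.613. Of 17 tested hypoxia targets, ANGPTL4 alone fell over all genes tested (log2 change -0.63, adjusted p = 0.0320) and 1 was lower adjusted over the list alone. With the block 6 were lower and 2 higher, and the list's camera test had an adjusted p of 0.152, or 0.0367 without replicate 1 of complete medium.

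Some nucleotide synthesis genes fell. Of 21 tested genes of purine and pyrimidine synthesis, 5 were lower and 0 higher over all genes tested, 10 were lower adjusted over the list alone and 11 with the block. RRM2, the small subunit of ribonucleotide reductase, fell from 193.2 ± 28.5 to 115.3 ± 10.8 CPM (n = 3), a log2 change of -0.74 (SE 0.107, adjusted p = 0.0217). TK1, thymidine kinase, fell from 111.5 ± 12.6 to 73.7 ± 7.97 CPM (log2 change -0.60, adjusted p = 0.0217). ADSS2 and ADSL, enzymes of AMP synthesis, fell by 0.49 and 0.33 (adjusted p = 0.0246 and 0.0312). The camera test gave an adjusted p of 0.000241, with 0.735 by an estimated correlation and 0.0505 by fry's direction test.

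Some ribosome assembly factors and respiratory chain subunits fell. Of 25 tested factors of ribosome biogenesis, 5 were lower and 0 higher over all genes tested, 8 were lower adjusted over the list alone and 10 with the block. NOP56 fell from 146.3 ± 21.2 to 93.7 ± 2.55 CPM (log2 change -0.64, adjusted p = 0.0217), and PES1, BOP1 and GAR1 fell by 0.39, 0.39 and 0.43. The list's camera test had an adjusted p of 0.0177, and of 0.735 with an estimated correlation and 0.182 by fry's direction test. By camera it was 0.0779 without replicate 2 of the deprived medium, and 0.0808 with the block and a correction for GC content and transcript length. Of 32 tested nuclear genes of oxidative phosphorylation, 3 were lower over all genes tested, namely NDUFV1, CYC1 and UQCRC2, by 0.48, 0.31 and 0.38. UQCRC2 missed the threshold by library totals (adjusted p = 0.0513) and by limma voom (0.0521). Adjusted over the list alone 4 were lower and 1 higher, and with the block 9 and 2. The camera adjusted p was 0.0343, and 0.765 with an estimated correlation. This call was lost by fry's direction test (adjusted p = 0.243), without replicate 2 or 3 of complete medium (adjusted p = 0.290 and 0.0538), without replicate 1 of the deprived medium (0.209), on log2 FPKM and log2 TPM (0.0614 and 0.0746), and with the block and the GC and length correction (0.246).

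Of 21 tested targets of NRF2, the regulator of antioxidant genes, 2 were lower and 0 higher over all genes tested, 5 were lower adjusted over the list alone, and 7 were lower and 2 higher with the block. These were SLC7A11, given above, and TALDO1 of the pentose phosphate pathway, which fell from 173.7 ± 20.7 to 121.0 ± 17 CPM (log2 change -0.52, adjusted p = 0.0343). TXNRD1 had a log2 change of -0.30 (adjusted p = 0.0501, and 0.00628 with the block) and GCLC one of -0.31 (adjusted p = 0.0612, and 0.00420 with the block). The list's camera adjusted p was 0.0218, and 0.557 with an estimated correlation. Without replicate 1 of complete medium it was 0.0508, without replicate 1 of the deprived medium 0.0643, without both 0.0911, and with the block and the GC and length correction 0.0567.

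Of 21 tested targets of p53, 7 were higher and 0 lower over all genes tested, 9 were higher adjusted over the list alone and 10 with the block. The other 14 were not called over all genes tested, and 19% of the 21 had a negative log2 change. CDKN1A, an inhibitor of cyclin-dependent kinases (NCBI Gene 1026, chromosome 6, 36676463 to 36687332), rose from 102.6 ± 13.7 to 145.3 ± 9.40 CPM (n = 3), a log2 change of 0.50 (SE 0.094, adjusted p = 0.0246). ZMAT3, an RNA-binding protein, rose from 106.7 ± 15.6 to 166.8 ± 13.9 CPM, a log2 change of 0.65 (SE 0.106, adjusted p = 0.0217). AEN, an exonuclease, rose by 0.48 (adjusted p = 0.0255). TP53INP1 rose by 1.79 (adjusted p = 0.0217) at a low level, from 0.461 ± 0.0322 to 1.61 ± 0.229 CPM. The camera test gave an adjusted p of 0.00429 for the list, in the higher direction. With an estimated correlation its adjusted p was 0.557.

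Cell cycle genes gave a mixed picture. Of 24 tested genes of DNA replication, CDC45 and POLA1 fell over all genes tested, by 0.62 and 0.31 (adjusted p = 0.0217 and 0.0265), and 2 were lower adjusted over the list alone. The list's median log2 change was 0.06 and its camera adjusted p 0.762, so these members and the median differed in sign. With the block 3 were lower and 1 higher. Of 24 tested mitosis genes, 0 were called over all genes tested and 0 adjusted over the list alone, with a camera adjusted p of 0.159. With the block 10 were lower and 1 higher, and the camera adjusted p was 0.00480, or 0.722 with an estimated correlation. Without the block the list also passed when replicate 1 of complete medium (adjusted p = 0.00178) or replicate 2 or 3 of the deprived medium (0.0492 and 0.00939) was left out. NUF2, BUB1 and CCNA2 had log2 changes of -0.44, -0.30 and -0.37 (adjusted p = 0.114, 0.190 and 0.231, and 0.00141, 0.00370 and 0.00224 with the block). AURKA had a log2 change of 0.21 (adjusted p = 0.297, and 0.0156 with the block).

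Genes whose products attract or polarise macrophages did not pass the test. Of 21 tested members, 0 were called over all genes tested, 0 were called adjusted over the list alone, and the camera adjusted p was 0.451. With the block 3 were higher and 4 lower. CCL2 was at 1.64 ± 0.550 CPM in complete medium and 2.84 ± 1.68 CPM without serine and glycine, a log2 change of 0.79 (SE 0.419, adjusted p = 0.255). CSF1 had a log2 change of 0.20 (SE 0.336, adjusted p = 0.746) and CXCL8 one of -0.52 (SE 0.238, adjusted p = 0.187), at about 2 to 3 CPM each. CXCL2 was at 21.5 ± 4.34 and 13.9 ± 2.46 CPM (log2 change -0.63, adjusted p = 0.0504, and 0.0105 with the block). HMGB1 and TGFB3 had log2 changes of -0.25 and 0.49 (adjusted p = 0.141 and 0.147, and 0.00549 and 0.0359 with the block). CSF2, TNF, CXCL10 and SPP1 had at most 3 rounded counts in any library, below the filter, so a change in them was not detectable at this depth.

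Inflammatory, interferon and antigen presentation genes were mostly not called. Of 17 tested NF-kB targets, 0 were called over all genes tested or adjusted over the list alone, and with the block 3 were higher and 1 lower (camera adjusted p = 0.598). Of 30 tested interferon genes, 2 were lower and 0 higher over all genes tested, among them IFI35, which fell by 0.44 (adjusted p = 0.0250). There were also 2 lower adjusted over the list alone, and 3 were lower and 4 higher with the block (camera adjusted p = 0.762, or 0.0239 and higher without replicate 1 of complete medium). Of 11 tested MHC genes, 0 were called over all genes tested, over the list alone or with the block (camera adjusted p = 0.762). Of 17 tested immediate early genes, 0 were called in any of these ways (camera adjusted p = 0.762).

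Among lipid synthesis genes, 3 rose and 2 fell over the 4 lists tested. Of 25 tested cholesterol genes, CYP51A1 and SC5D rose by 0.28 and 0.24 (adjusted p = 0.0286 and 0.0477) and MVD fell by 0.37 (adjusted p = 0.0366). Adjusted over the list alone the counts were also 2 higher and 1 lower, with the block 5 and 3, and the camera adjusted p was 0.329, or 0.0367 without replicate 1 of the deprived medium. Of 18 tested genes of sphingolipid synthesis, a pathway that begins with serine, DEGS1 rose by 0.26 and ORMDL2 fell by 0.40 (adjusted p = 0.0472 and 0.0296). The counts adjusted over the list alone were 1 and 1, with the block 1 higher and 2 lower, and the camera adjusted p was 0.716. Of 7 tested genes of phosphatidylserine handling, 0 were called over all genes tested or adjusted over the list alone, and 1 was higher with the block (camera adjusted p = 0.536). Of 13 tested genes of fatty acid synthesis, 0 were called over all genes tested or adjusted over the list alone, and 2 were higher and 1 lower with the block (camera adjusted p = 0.952, lower, with a median log2 change of 0.01). ACLY had a log2 change of -0.30 (adjusted p = 0.0577, and 0.00263 with the block) and SCD one of 0.26 (adjusted p = 0.112, and 0.0197 with the block).

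Of 25 tested genes of autophagy and lysosomes, ATG7 and TFE3 fell by 0.46 and 0.22 (adjusted p = 0.0217 and 0.0444, the latter 0.0655 by library totals). Adjusted over the list alone 2 were lower and 1 higher, and with the block 4 and 3. The camera adjusted p was 0.762, and the list's median and mean log2 change, 0.03 and -0.01, differed in sign. Of 14 tested heat shock genes, DNAJA1 rose from 386.0 ± 42.5 to 509.1 ± 30.2 CPM (log2 change 0.40, adjusted p = 0.0320). It was also the sole call adjusted over the list alone, 4 were higher and 1 lower with the block, and the camera adjusted p was 0.187.

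Some epithelial genes fell. Of 18 tested genes of squamous epithelium, 3 were lower and 0 higher both over all genes tested and adjusted over the list alone, and 5 were lower with the block. ITGB4, the integrin of hemidesmosomes, fell from 76.0 ± 6.53 to 47.1 ± 3.40 CPM (n = 3), a log2 change of -0.69 (SE 0.083, adjusted p = 0.0184). KRT19 and KRT16 fell by 0.48 and 0.63 (adjusted p = 0.0217 and 0.0246). KRT16 shares near-identical sequence with other keratin genes, so its value is uncertain. The camera adjusted p of the list was 0.0132, and 0.557 with an estimated correlation. Of 13 tested genes of epithelial-mesenchymal transition, ITGA5 alone fell over all genes tested, by 0.35 (adjusted p = 0.0217), 1 was lower adjusted over the list alone and 3 were with the block (camera adjusted p = 0.288).

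Markers of other cell types were few. Of 6 tested fibroblast markers 0 were called over all genes tested, and 1 was higher and 1 lower both adjusted over the list alone and with the block (camera adjusted p = 0.598). Of 3 tested endothelial markers 0 were called in any of these ways (camera adjusted p = 0.952). Of 16 immune markers 2 could be tested. CD68, a lysosomal protein used as a macrophage marker, fell from 53.9 ± 5.29 to 37.0 ± 2.15 CPM (log2 change -0.54, adjusted p = 0.0217). CD14 was at 0.460 and 1.22 CPM (adjusted p = 0.0764, and 0.0404 with the block). There were 1 higher and 1 lower adjusted over the list alone, and no set test was run on 2 genes.

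Of 38 tested ribosomal protein genes, RPL15 rose by 0.31 (adjusted p = 0.0467), 0 were called adjusted over the list alone, and 3 were higher and 6 lower with the block. The camera adjusted p was 0.436, or 0.0492 and 0.0426 and lower without replicate 2 or 3 of the deprived medium. Genes of this kind share sequence with processed copies and are uncertain. They held 2.35, 2.62 and 2.61% of the counts in complete medium and 2.11, 2.65 and 2.63% without serine and glycine, so the libraries numbered 1 stood lowest in each medium. Of 7 tested replication histone genes 0 were called over all genes tested or over the list alone, and 1 was higher and 1 lower with the block (camera adjusted p = 0.536). Mitochondrially encoded genes are not analysed here.

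**Figure D3:**
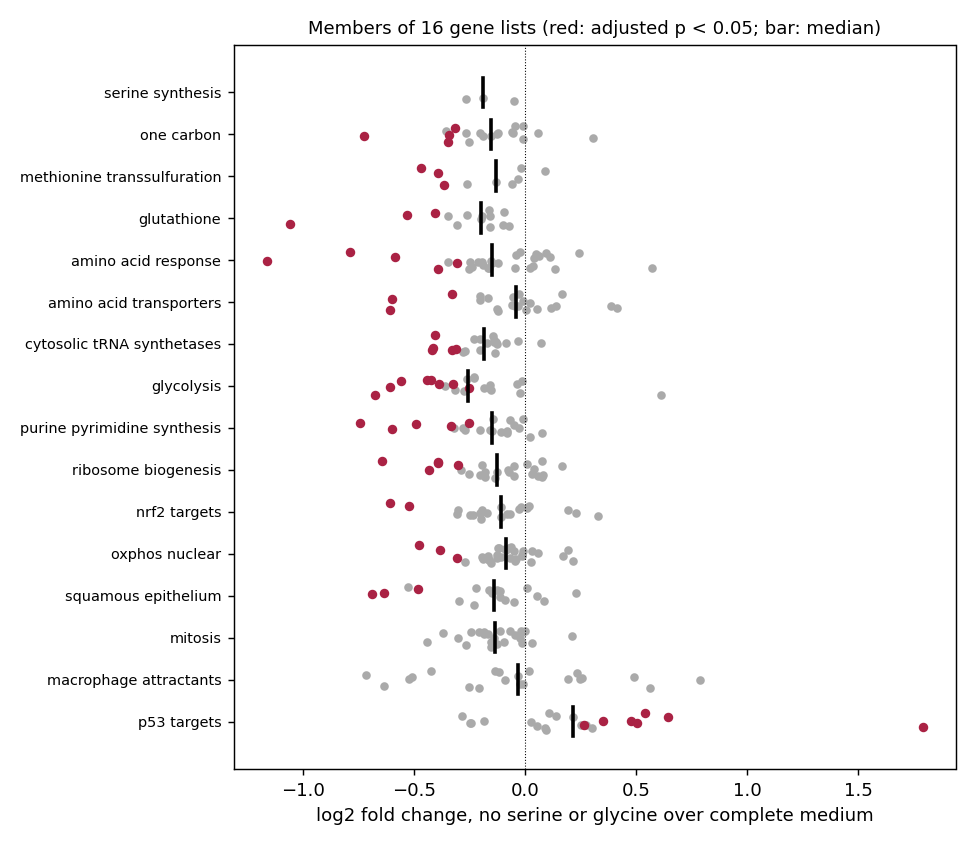
Log2 fold change of each tested member of 16 gene lists (x axis, without serine and glycine over complete medium), with called members in red, the others in grey and the list's median as a black bar. The medians range from -0.26 for glycolysis to 0.22 for p53 targets.

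Among called genes at 5 CPM or more in the higher group, with no overlap between the media, the largest rises were in COL11A2, C11orf42, DCAF4L1, QRICH2, AOC3, ADORA2A, TDRD6, AOC2, ISYNA1 and FGF11. COL11A2, a chain of type XI collagen (NCBI Gene 1302, chromosome 6, 33162694 to 33193519), rose from 3.48 ± 1.39 to 11.2 ± 3.52 CPM (n = 3), 3.22-fold (log2 change 1.69, SE 0.313, adjusted p = 0.0251). The other 9 rose by 0.82 to 1.08 on the log2 scale. AOC2 and AOC3 are neighbouring paralogs on chromosome 17, so their reads may be shared and both values are uncertain. ISYNA1, which makes inositol phosphate from glucose 6-phosphate, rose from 5.85 ± 1.78 to 10.7 ± 0.721 CPM.

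Within the same limits the largest falls were in ARFRP1, REX1BD, FGF21, SERPINB1, PGGHG, ECM2, REEP6, ABHD11, PYCR3 and REXO5, with log2 changes of -1.33 to -0.96. SERPINB1, an inhibitor of neutrophil proteases (NCBI Gene 1992, chromosome 6, 2832332 to 2841863), was the most abundant of them and fell from 65.8 ± 11.5 to 30.5 ± 3.25 CPM (log2 change -1.11, SE 0.126, adjusted p = 0.0184). PYCR3, an enzyme of proline synthesis, fell from 7.02 ± 0.564 to 3.59 ± 1.41 CPM (adjusted p = 0.0411). By p-value the leading genes that fell were ACAD9, a mitochondrial assembly factor and dehydrogenase, SERPINB1, ITGB4, EPPK1 and the nucleoside carrier SLC29A2. ACAD9 fell from 85.0 ± 6.65 to 53.8 ± 0.498 CPM (log2 change -0.66, adjusted p = 0.0184). The leading genes that rose were FBXO9, TMEM170B, DPF2, ZNF862 and C5orf51. FBXO9, an F-box protein, rose from 24.4 ± 3.27 to 39.9 ± 1.2 CPM (log2 change 0.71, adjusted p = 0.0184).

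Of 34 lists tested with camera, 12 were called, 11 lower and 1 higher, and 13 with the block, the mitosis list being the added one. With an estimated correlation 0 of the 34 were called, and the lowest adjusted p was 0.557. By the direction test of fry, which asks whether a list's own genes move one way, 7 lists passed: the folate cycle, glutathione, glycolysis, p53, NRF2 and squamous epithelium lists, which were also called by camera, and the amino acid transporters, which were not. The other 6 lists called by camera did not pass it, namely methionine and transsulfuration, amino acid response, cytosolic tRNA synthetases, nucleotide synthesis, ribosome biogenesis and oxidative phosphorylation.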

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

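The GC and length correction, the omission of both libraries numbered 1 and the omission of whole pairs were chosen after seeing the data. With the replicate block 3044 genes were called (1387 higher, 1657 lower, 80 at least 2-fold), and 136 of the genes chosen by the naming rule against 87 without it. Beyond the blocked values given with the results, the block changed no other call among the genes and lists named there, and it turned no direction. The block with GC and length correction called 3376 (1666 higher, 1710 lower, 84 at least 2-fold, 146 named). Without both libraries numbered 1 there were 3643 (1696 higher, 1947 lower, 141 at least 2-fold, 137 named). The block called 5408 genes without pair 1 (2649 higher, 2759 lower, 163 at least 2-fold, 150 named), 1642 without pair 2 (687 higher, 955 lower, 60 at least 2-fold) and 1164 without pair 3. The block and the omission of libraries leave less from which to estimate the spread between libraries. Higher counts in these fits are therefore not stronger evidence. limma on log2(FPKM + 1) called 506 (187 higher, 319 lower, 6 at least 2-fold), and on log2(TPM + 1) 148 (45 higher, 103 lower, 7 at least 2-fold, 32 named). The share of lower calls was 60.7% with TMM, 51.3% with library totals and 69.6% with TPM. DESeq2 called 1228 genes, 21 of them at least 2-fold with its own estimates. Against a fold of 1.2, edgeR's glmTreat called 0 higher and 0 lower genes, and 901 at an unadjusted p under 0.05. Its construction, which asks for more than a small change, lowers the count. In the FPKM and TPM fits, adding 1 before the log shrinks the fold changes of low values, which can lower the 2-fold counts. These fits tested 11371 and 11985 genes, and DESeq2 gave adjusted p-values for 11298. How far these differences account for the counts was not tested, nor was the cause for the other settings. Camera with an estimated correlation called 0 lists, and fry 7.

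Leaving out each library in turn gave 0 to 1737 changed genes, 0 to 758 higher, 0 to 979 lower, 0 to 82 at least 2-fold, 0 to 102 named genes and 9 to 14 lists. The lists of the folate cycle, glutathione, tRNA synthetases, glycolysis, nucleotide synthesis, p53 targets and squamous epithelium passed in 6 of 6 such fits. Those fits share libraries and the preset correlation with the main fit, so this is not independent evidence. With an estimated correlation 0 lists were called. Over all settings, 3391 comparisons of a named gene with its main result gave 2613 on the same side of the threshold, 442 that fell short of it, 336 that newly passed and 0 reversed, with 23 changes of sign among genes called in neither. For lists, 612 of 675 stayed, 45 fell short, 18 newly passed and 0 reversed, with 33 changes of sign among uncalled lists. Other pseudocounts and filters for FPKM or TPM were planned for a table without counts and were not run. Depth limits the macrophage attractants below the filter, where a change was not detectable.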

Other observations

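Grouping by symbol family, the correction for GC content and length, the test of exchanged labels and the zinc finger test were chosen after the results were seen. Of 155 symbol families with at least 10 tested members, 2 passed camera without the block. The ZBTB family, 40 genes with a median log2 change of 0.16, had an adjusted p of 0.0662, and of 0.0439 with the block. Of 399 zinc finger genes named ZNF, 24 rose and 2 fell over all genes tested, with a median log2 change of 0.14 (adjusted p = 1.99e-06, and 0.956 with an estimated correlation). With the block 84 rose and 6 fell, and after the GC and length correction 88 and 6. ZNF862 rose from 34.9 ± 4.62 to 53.2 ± 2.13 CPM (adjusted p = 0.0217). Named after their values were seen, ZNF420 and ZNF800 rose by 0.60 and 0.32 on the log2 scale, and ZNF280C and ZNF76 fell by 0.71 and 0.65. Of 12 keratin genes 3 fell and 0 rose, with a median of -0.22 (adjusted p = 0.0159, and 0.956 with an estimated correlation). By fry's direction test neither the ZNF nor the keratin family passed (adjusted p = 0.0947 each). The MYO and KLHL families, not called by camera, passed fry (adjusted p = 0.0413 and 0.0479). Among 14 genes of the PSMD family, which encode proteasome subunits, 4 fell, and the family was not called. Named after their values were seen, these were PSMD8 (log2 change -0.49, adjusted p = 0.0217), PSMD5, PSMD13 and PSMD7.

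Transcript length went with direction. The median length was 4235.5 bases for genes called higher, 2416 for genes called lower and 3463 for genes not called, with median GC contents of 45.8, 55.0 and 48.6%. Across genes, which are not independent replicates, the log2 change had a Spearman correlation of 0.174 with length and -0.077 with GC content. After a per-library correction for both in the blocked fit, 1 of the 2 families called without the block was past the threshold. The ZBTB family was not (adjusted p = 0.103 by camera). For keratins the median log2 change went from -0.21 (quartiles -0.47 and -0.14) in the blocked fit to -0.13 (-0.37 and -0.07), the adjusted p from 0.0154 to 0.0837, and the lower genes from 6 to 4 of 12. The call ended as the median moved toward 0 but stayed below it, so part of the keratin shift went with length or GC as fitted. The error of that part was not estimated, so its size stays open. The ZNF family had a median of 0.14 before and 0.15 after the correction and kept an adjusted p of 8.76e-05, which argues against such a trend as the whole source. A response of zinc finger genes to the medium is one hypothesis, untested here, as are reads shared between similar genes.

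The 5 ATF4 targets that fell in a medium without serine and glycine are a pattern to follow up. From the blocked fit to the GC and length correction, their log2 changes went from -0.77 to -0.71 (SE 0.072) for PCK2, -0.58 to -0.55 (SE 0.048) for ASNS, -1.16 to -1.06 (SE 0.163) for FGF21, -0.39 to -0.34 (SE 0.047) for CTH and -0.31 to -0.34 (SE 0.061) for STC2. The correction ended 414 of the 3044 blocked calls, added 746, and left all 5 of these, at most 0.10 from their blocked values. It moved genes little, with a 95th percentile of 0.1 for the absolute shift, so these picked genes were likely to stay called. The fitted length and GC trend moved these 5 genes by at most 0.10, less than their changes. As they were picked as called, their staying called does not test such a trend as a cause. An exchange of labels between single libraries of the media would make another grouping the true one, but 0 of the 9 exchanges of 1 library of each medium called as many genes as the given labels, and the highest called 0 against 872. A reversal of all 6 labels has no test in these data and stays open. The response may already have been active in complete medium, which lacks other non-essential amino acids, since the list's median expression percentile there was 82.5, but that cannot be told apart from a high constitutive level.

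Genes that changed at least 2-fold were low in abundance, with a median of 2.13 CPM for the 27 that rose and 3.82 for the 11 that fell, against 48.2 for all called genes. Wider errors at low counts could place rare genes past 2-fold in either direction, which was not tested. For the rises, background reads from unspliced RNA or genomic DNA could raise rare transcripts together. However, the genes under 1 CPM other than these 27, 2052 with at least 10 counts in all, had a median log2 change of -0.023. Its 95% bootstrap interval was -0.024 to 0.030. The bootstrap resampled genes, so the interval leaves out the spread between libraries. The 27 genes had a median log2 change of 1.238 in the blocked fit and 1.305 after the GC and length correction. They were picked for a log2 change of at least 1, and the correction was fitted on genes with a mean log2 CPM over 2. On that log2 scale their median abundance lies lower, so the correction cannot decide on a length or GC trend for them. Low counts leave their size uncertain, and a biological response of these genes is a hypothesis.

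The 6 libraries form 10 splits of 3 against 3, so a share under 0.05 cannot be reached. The real split called 872 genes and the highest of the others 0, with 1 of 10 splits giving as many. For lists, 3 of 10 splits called as many as the real 12, and the highest of the others called 14. The other splits that part all 3 numbered pairs called 0 genes each with the block, against 3044, and 3, 3 and 6 lists without it. The splits with 12 and 14 lists put both libraries numbered 1 in the same group. So did the splits that joined deprived library 1 to libraries 1 and 2, or 1 and 3, of complete medium, and these called 6 and 4 lists.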
